A study of Mus musculus with 8 samples.

How the data were processed

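Gene expression was measured by RNA sequencing in 8 mouse liver libraries. The labels give the strain as C57BL/6 and the treatment of each sample: a normal diet (ND, 2 libraries), a high-fat diet (HFD, 3 libraries) and a high-fat diet with white tea extract (HFD_WTE, 3 libraries). Group and replicate number were taken from the sample titles. The labels do not say that the libraries of a group came from separate mice, so the p-values measure the spread between these samples, which may be technical. Per the labels' protocols, RNA was isolated with TRIzol from whole liver and selected with oligo dT. The same protocol names kidney tissue once, so kidney markers were checked in each library.

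Per the submitters' processing notes, Trim Galore 0.6.6, Salmon 1.4.0 and the mm10 genome build were used. The annotation release behind the gene models is not given in the sources used here. Each deposited file holds, per the file headers, an estimated count (the reads Salmon assigned to a gene, which need not be whole), the TPM value (transcript abundance scaled to a fixed total per library) and an effective length for each of 22279 genes. Salmon divides reads among similar transcripts by a statistical model, so values of near-identical genes (the Mup, Cyp2b, Ugt2b, Serpina1, Selenbp and haemoglobin genes among those named here) are uncertain as to which copy the reads came from. The deposited TPM values are relative to the sum within a library, so a gene class that takes a large share lowers the TPM of all others.

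Gene symbols came from a table of gene identifiers: 21610 identifiers matched with their version and 22237 without it. Where 2 rows shared a symbol, the row with more reads kept it, which concerned 26 other rows. Coordinates are those of GENCODE mouse release 21 on GRCm38, the assembly that mm10 names, and are 1-based. The estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with the groups (minimum count 10), which left 13127 genes with at least 99.96% of the reads of each library. Library sizes were scaled with TMM, and edgeR 4.0.16 (R 4.3.3) fitted a quasi-likelihood model with a mean for each group to all 8 libraries, so that the groups shared their estimate of the spread with 5 residual degrees of freedom. Each comparison used glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the tested genes. A gene was called when its adjusted p was under 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Expression levels are CPM (counts scaled to a fixed total per library, with TMM) with the SD over the libraries of a group.

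The design, the tests, the named-gene rule, 20 pathway lists and 12 cell marker lists were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on the edgeR fit, with a preset inter-gene correlation of 0.01 and adjustment over all 32 lists within a comparison. Members are counted as risen, fallen or not past 0.05, first adjusted over all tested genes and then adjusted over the list alone. Some genes are in more than 1 list. Members with too few reads were not tested, which left 8 of 17 female-biased genes, 2 of 16 kidney markers and 1 of 7 adipocyte markers. The rule for named genes took, in each comparison, the 5 largest rises and the 5 largest falls among called genes whose groups did not overlap in CPM and whose higher group averaged at least 2 CPM (predicted gene models left out), the member with the smallest p from each pathway list, the same from each cell list past 0.05, and always Scd1, Fasn, Srebf1, Cpt1a, Cidea, Cd36, Cyp7a1 and Fgf21. In HFD_WTE against ND, members of pathway lists and the fixed genes were named only if called, while cell list members were named as in the other comparisons. A gene that the rule took is not reported here. Other genes, named to spell out a short count or single values, were chosen after their values were seen. For 3 or fewer reads in a group, ratios are of summed reads with an exact 95% interval that covers counting error only; against 0 reads, a floor of 3 reads over the group gave a lower bound.

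The fit was tested on simulated counts with the real means, library sizes and spread and 200 changed genes. For HFD against ND, fitted on 12948 genes, it recovered 23% of the 2-fold and 84% of the 4-fold changes. For HFD_WTE against HFD (12942 genes) it recovered 26% and 81%, and for HFD_WTE against ND (12974 genes) 17% and 78%. At most 7 calls in a comparison were false. The libraries held 18954071 to 24112000 estimated reads. Whether reads were counted by strand is not given in the sources used here, so a gene and an antisense partner may not be told apart. Chance values for comparisons that share libraries came from 50 simulated data sets with the diet difference kept and no extract effect, and 50 with no effect at all. Genes vary independently in these simulations. In the first kind the observed group differences were taken as true, so the simulations called more genes for the diet than the data did.

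The alternatives were DESeq2 1.42.0, other scalings (RLE, total counts, removal of mitochondrially encoded and Mup genes), other low-count filters, an effective length offset, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), a fit of only the 2 groups compared, the replicate number as a block, a 2-fold threshold, and leaving out each library. limma-voom with sample weights and a minimum of 5 tested members per list were added after the data were seen; the latter had been used by mistake in a first run. Fits in which the HFD or the ND libraries were split, so that 2 comparisons shared no library, were also added then, with TMM and the spread estimated over all 8 libraries. Pairs of replicate libraries differed by far more than sampling noise, with a chi-square per degree of freedom of at least 42.4, so all 8 were kept.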

Results

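Liver transcriptomes were compared between mice on a normal diet (ND, 2 libraries), a high-fat diet (HFD, 3 libraries) and a high-fat diet with white tea extract, a preparation of minimally processed tea leaves (HFD_WTE, 3 libraries). The libraries held 18954071 to 24112000 estimated reads. The ND libraries differed most from each other within a group: their Spearman correlation over genes was 0.952, against 0.972 to 0.985 within HFD and 0.971 to 0.982 within HFD_WTE. ND replicate 1 was closer to HFD replicates 1, 2 and 3 (0.966, 0.9597 and 0.9568) than to ND replicate 2. With HFD_WTE replicates 1, 2 and 3 it correlated at 0.949, 0.9555 and 0.9667. ND replicate 2 correlated best with ND replicate 1. The first principal component, with 34.2% of the variance, set ND replicate 2 and then ND replicate 1 apart from the other 6 libraries. Mitochondrially encoded genes took 31.2 ± 5.29% (SD, n = 2) of the reads in ND, 13.0 ± 1.57% (SD, n = 3) in HFD and 15.6 ± 0.467% (SD, n = 3) in HFD_WTE. The Mup family, which encodes the major urinary proteins secreted by the liver, took 3.19 ± 1.36%, 13.3 ± 0.209% and 3.82 ± 1.39%.

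The kidney list summed to 0.719 ± 0.0968 TPM in ND, 0.542 ± 0.232 in HFD and 0.639 ± 0.220 in HFD_WTE, the pancreatic list to at most 1.17 TPM and the skeletal muscle list to at most 5.83 TPM in a library. The adipocyte list summed to 10.4 ± 13.1 TPM in ND, 42.8 ± 19.3 in HFD, with 64.8 in HFD replicate 1, and 2.74 ± 2.02 in HFD_WTE. The hepatocyte list summed to 39865 ± 4121, 50099 ± 11813 and 58244 ± 15391 TPM. Mitochondrially encoded genes took 467141 TPM on average in ND, 220511 in HFD and 260061 in HFD_WTE. This lowers the TPM of all other genes most in ND, so marker sums in TPM are not on one scale between the groups. By camera on the edgeR fit, the hepatocyte list passed in no comparison. All 8 libraries held reads of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, at least 1493 estimated reads in sum. Nnt, a gene disrupted in a C57BL/6 substrain, summed to 9.96 ± 1.88, 8.23 ± 3.12 and 10.2 ± 0.708 TPM. Macrophage markers reached 523 TPM in ND replicate 2, 215 in ND replicate 1 and at most 202 elsewhere. Erythroid markers reached 1899 TPM in ND replicate 1 and 914 in ND replicate 2, and at most 648 elsewhere.

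**Figure D1:**
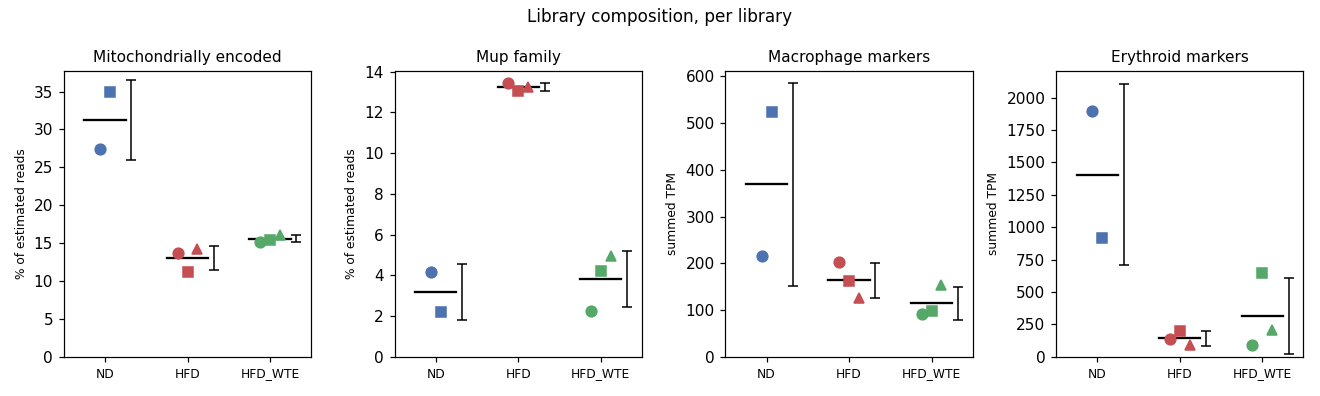
Share of estimated reads (%) from mitochondrially encoded and Mup genes, and summed TPM of macrophage and erythroid markers, for each library by group. Points are libraries (circle, square and triangle for replicates 1, 2 and 3), horizontal lines are means and bars beside them the SD; the HFD libraries lie together at 13.3 ± 0.209% for the Mup genes, and ND has the highest mitochondrially encoded share.

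The first comparison asked what the high-fat diet changed in the liver. Cyp2b9, a cytochrome P450 with higher expression in females, fell from 27.3 ± 0.935 CPM (SD, n = 2) in ND to 0.241 ± 0.253 CPM (SD, n = 3) in HFD, a log2 fold change of -6.79 ± 0.63 (SE, edgeR adjusted p = 0.00171). Lpl, which hydrolyses triglycerides of lipoproteins, fell from 44.1 ± 5.09 to 10.3 ± 0.690 CPM (-2.10 ± 0.21, adjusted p = 0.00293). Moxd1 rose from 0.0281 ± 0.0398 to 12.4 ± 1.35 CPM (adjusted p = 0.00171); with 1 read in ND, the ratio of summed reads was 518, with an exact 95% counting interval of 92.6 to 20500. Fabp1, a fatty acid carrier of hepatocytes, rose from 1514 ± 164 to 4588 ± 1064 CPM, and Cyp3a11, an enzyme of drug oxidation, fell from 2292 ± 116 to 390 ± 197 CPM (adjusted p = 0.04 and 0.0368).

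In all, 144 genes were called, 75 higher and 69 lower in HFD. An unadjusted p under 0.05 was reached by 2383 genes, where 656 would be expected if no gene differed. The other largest rises were Selenbp2 (log2 fold change 4.35 ± 0.67), Mup11 (3.71 ± 0.75), a second gene model named Sssca1 (3.49 ± 0.66) and Tmem28 (3.20 ± 0.54). The other largest falls were Cyp2b10 (3 reads in HFD against 116 in ND, a ratio of 57.9 with an exact interval of 19.3 to 285), Hamp2 (-4.91 ± 0.99), and the haemoglobin genes Hbb-bs (-4.68 ± 0.92) and Hbb-bt (-4.31 ± 0.89). The genes with coordinates here are protein-coding and on GRCm38. Moxd1 lies on chromosome 10 (24223517 to 24302790), Cyp2b9 on chromosome 7 (26173411 to 26210661), Lpl on chromosome 8 (68880491 to 68907448) and Selenbp2 on chromosome 3 (94693556 to 94704413).

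Of 17 liver genes with male-biased expression, 3 rose in edgeR (Selenbp2, Ugt2b38 and Serpina1e), none fell and 14 did not pass, while DESeq2 called 11 as risen; adjusted over the list alone, 13 rose. The list median was 1.42 on the log2 scale (camera adjusted p = 3.92e-13, and adjusted p = 0.214 with an estimated correlation). Selenbp2 went from 26.8 ± 17.0 to 545 ± 353 CPM. Of 8 measured female-biased genes, 2 fell (Cyp2b9 and Fmo2) and 6 did not pass, with 5 fallen when adjusted over the list alone (camera adjusted p = 4.05e-08, and adjusted p = 0.121 with an estimated correlation). All 22 measured Mup genes had positive fold changes under every scaling that kept them (median 2.42 with TMM). In edgeR, 1 of them was called (Mup11), against 9 in DESeq2, 2 in limma-trend on log2(TPM + 1) and 1 in limma-voom with sample weights, and their copies share reads.

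The 24 genes of cholesterol synthesis all had positive fold changes in HFD, with a median of 1.15. None passed in edgeR over all genes, while 18 had an unadjusted p under 0.05, DESeq2 called 8 as risen, limma-trend on log2(TPM + 1) and limma-voom with sample weights called 0, and 14 rose when adjusted over the list alone (camera adjusted p = 1.53e-12, and adjusted p = 0.33 with an estimated correlation). Nsdhl, a demethylating enzyme of the pathway, measured 3.81 ± 1.57 CPM in ND and 28.5 ± 14.3 CPM in HFD (adjusted p = 0.0596). The bile acid list had a median of 0.58 (19 genes, none called in edgeR, 6 at an unadjusted p under 0.05, 3 risen in DESeq2, 3 risen over the list alone). Its camera adjusted p was 0.00366, with adjusted p = 0.592 under an estimated correlation and 0.659 without ND replicate 2; its leading member Cyp7b1 measured 88.0 ± 3.56 and 259 ± 58.4 CPM. The endoplasmic reticulum list passed camera (adjusted p = 0.0281) with none of 20 genes called in edgeR, 4 at an unadjusted p under 0.05, 2 risen in DESeq2 and 0 over the list alone. That adjusted p was 0.657 with an estimated correlation, 0.426 without ND replicate 1 and 0.0774 without HFD replicate 2. Calr, a chaperone, measured 267 ± 50.8 CPM in ND and 553 ± 47.3 CPM in HFD.

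Of 18 macrophage markers, Vsig4 fell from 23.3 ± 14.5 to 6.81 ± 0.605 CPM and 17 did not pass, with 16 fallen when adjusted over the list alone (camera adjusted p = 5.84e-12, and adjusted p = 0.285 with an estimated correlation). Of 15 lymphocyte markers, Gzma, a granule protease of cytotoxic cells, fell, as did 6 over the list alone (camera adjusted p = 1.30e-06, and adjusted p = 0.265 with an estimated correlation). Of 16 inflammatory genes, the chemokine Ccl5 fell from 9.62 ± 2.78 to 2.15 ± 1.17 CPM, and 11 fell and 1 rose over the list alone. Of 22 interferon response genes, Gbp2 and Usp18 fell, and 10 fell and 1 rose over the list alone. Camera gave the inflammatory and interferon lists an adjusted p of 6.38e-06 and 1.30e-07. With an estimated correlation, adjusted p = 0.341 and 0.38, and without ND replicate 2, which had the highest macrophage markers, adjusted p = 0.142 and 0.175. The cell cycle list passed camera (adjusted p = 0.000804) with none of 16 genes called in edgeR, 6 at an unadjusted p under 0.05, 1 fallen in DESeq2 and 2 over the list alone. That adjusted p was 0.38 with an estimated correlation and 0.19 without ND replicate 2; Mki67, a proliferation marker, measured 7.52 ± 6.97 CPM in ND and 1.43 ± 0.516 in HFD.

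Of 18 stellate cell and matrix genes, Col1a2, a chain of type I collagen, fell from 15.6 ± 0.897 to 4.55 ± 0.616 CPM, and 2 fell over the list alone (camera adjusted p = 1.56e-05, adjusted p = 0.265 with an estimated correlation and 0.0776 without ND replicate 1). The 4 haemoglobin genes fell out of 5 erythroid markers (camera adjusted p = 6.38e-06, and adjusted p = 0.285 with an estimated correlation). Of 22 genes of xenobiotic metabolism, Cyp2b10 and Cyp3a11 fell, with 8 fallen over the list alone (camera adjusted p = 0.00366, adjusted p = 0.592 with an estimated correlation and 0.653 without ND replicate 1). Of 13 mitochondrially encoded genes, 7 fell, led by mt-Co1 (-1.68 ± 0.28, adjusted p = 0.0367).

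The other 19 lists did not pass camera. Adjusted p was 0.0514 for fatty acid uptake and lipoproteins, 0.0653 for fatty acid oxidation, 0.0746 for circadian clock, 0.0939 for sinusoidal endothelium, 0.115 for fatty acid synthesis, 0.153 for lipid droplet, 0.187 for antioxidant and 0.304 for respiratory chain genes. It was 0.617 for glucose metabolism, 0.632 for PPAR-alpha targets, 0.634 for acute phase proteins, 0.93 for energy expenditure, and 0.2, 0.459, 0.452, 0.512, 0.593, 0.72 and 0.719 for adipocyte, neutrophil, pancreatic, cholangiocyte, kidney, muscle and hepatocyte markers. Within these lists, Fitm1, which promotes lipid droplet formation, rose from 21.9 ± 10.04 to 106 ± 12.6 CPM, and Got1, an aminotransferase, and Gsta2, a glutathione transferase, fell (adjusted p = 0.0416 and 0.0367). Other leading members were not called in edgeR: Fasn, which synthesises fatty acids, measured 42.6 ± 5.08 and 100.3 ± 12.3 CPM in ND and HFD, Orm3 17.4 ± 0.464 and 3.32 ± 0.648, Per2 46.9 ± 35.4 and 141 ± 26.5, Dio1 65.2 ± 34.3 and 172 ± 42.7, Bdh1 78.8 ± 25.4 and 144 ± 25.9, and Cox5a 106 ± 11.3 and 71.2 ± 14.0. DESeq2 called all of these but Cox5a (adjusted p = 0.179). In their lists it called 2 risen and 1 fallen gene for fatty acid synthesis, 3 fallen for acute phase proteins, 3 risen and 1 fallen for circadian clock, 1 risen and 1 fallen for energy expenditure, 1 risen for fatty acid oxidation and 0 for the respiratory chain, where edgeR called 0. At an unadjusted p under 0.05 these lists held 9, 3, 9, 3, 3 and 2 genes. Scd1 (1217 ± 370 and 924 ± 585 CPM), Srebf1 (51.1 ± 18.6 and 70.1 ± 19.3), Cpt1a (180 ± 1.92 and 209 ± 30.4), Cd36 (31.4 ± 2.32 and 28.9 ± 8.97), Cyp7a1 (10.6 ± 8.77 and 17.4 ± 8.39), Fgf21 (7.50 ± 3.95 and 23.3 ± 28.2) and Cidea (0.113 ± 0.159 and 1.12 ± 0.0435) did not pass in edgeR either, and of these DESeq2 called Cidea (adjusted p = 0.0447). Of the 20 calls named by the fixed rule, only those of Cyp2b9, Lpl and Moxd1 passed in every alternative run. The number of calls rested on single libraries: it was 724 without ND replicate 1, 51 without ND replicate 2, 64, 22 and 6 without HFD replicates 1, 2 and 3, and 48 and 85 without HFD_WTE replicates 2 and 3. Without HFD_WTE replicate 1 the number was 152. The HFD_WTE libraries enter this comparison only through the shared fit. DESeq2 called 733 genes, and with total counts in place of TMM 65.4% of the calls were higher in HFD, against 52.1%.

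**Figure D2:**
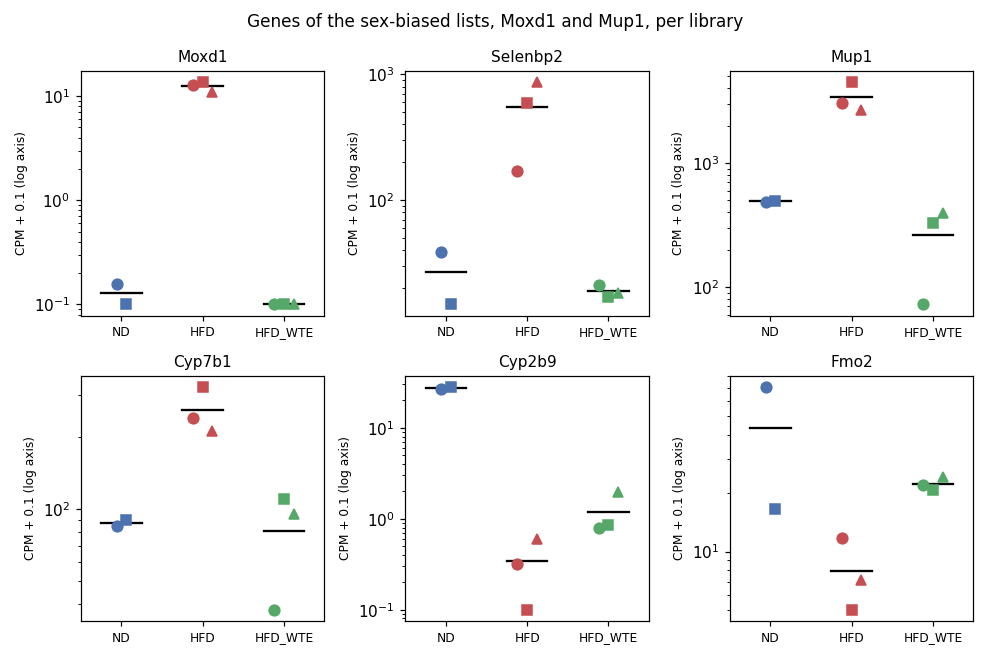
CPM + 0.1 (log axis) of Moxd1, of Mup1, of 2 genes of the male-biased list (Selenbp2, Cyp7b1) and of 2 of the female-biased list (Cyp2b9, Fmo2) in each library by group. Points are libraries (circle, square and triangle for replicates 1, 2 and 3) and lines are group means of CPM + 0.1; Moxd1 averages 12.4 CPM in HFD and 0 in HFD_WTE.

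The second comparison asked what the extract changed in mice on the high-fat diet. Moxd1, at 12.4 ± 1.35 CPM (SD, n = 3) in HFD, had no read in the 3 HFD_WTE libraries (edgeR adjusted p = 0.000271). Against a floor of 3 reads over the group it was at least 253-fold lower, and the exact 95% counting interval of the ratio began at 205. Selenbp2 fell from 545 ± 353 to 18.8 ± 2.18 CPM (log2 fold change -4.86 ± 0.57, adjusted p = 0.0197), Ugt2b38, a glucuronosyltransferase, from 9.99 ± 5.32 to 0.771 ± 0.299 CPM (-3.68 ± 0.47, adjusted p = 0.0271), and Mup1 from 3404 ± 975 to 265 ± 170 CPM (-3.68 ± 0.53, adjusted p = 0.0423). Slc22a26, a member of the organic anion transporter family, rose from 0.211 ± 0.0414 to 3.53 ± 2.04 CPM (4.03 ± 0.53, adjusted p = 0.0312) and Ppl, the cell junction protein periplakin, from 11.4 ± 1.54 to 37.5 ± 10.8 CPM (1.72 ± 0.24, adjusted p = 0.0358). These 6 were all the genes called. An unadjusted p under 0.05 was reached by 790 genes, where 656 would be expected if no gene differed.

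Male-biased liver genes were lower with the extract. All 17 had negative fold changes under every scaling that kept them (median -1.33 with TMM), as did the 14 left when the Mup genes were removed. Over all genes 2 fell in edgeR and 9 in DESeq2, and 10 fell over the list alone. Camera gave adjusted p = 1.01e-36, and this list alone passed with an estimated correlation (adjusted p = 0.0463). Female-biased genes were higher, with 8 of 8 fold changes positive under every scaling run, several of them from few reads. None was called in edgeR over all genes, 5 had an unadjusted p under 0.05, DESeq2 called 0 and 3 rose over the list alone (camera adjusted p = 4.21e-06, and adjusted p = 0.121 with an estimated correlation). Fmo2, a flavin monooxygenase, measured 7.84 ± 3.41 CPM in HFD and 22.2 ± 1.68 in HFD_WTE. All 22 Mup genes had negative fold changes under every scaling that kept them (median -2.24 with TMM). In edgeR, 1 of them was called (Mup1), against 12 in DESeq2, 10 in limma-voom with sample weights and 0 in limma-trend on log2(TPM + 1).

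Of 22 genes of xenobiotic metabolism, 6 rose over the list alone, with none called in edgeR over all genes, 7 at an unadjusted p under 0.05 and 2 risen in DESeq2. Camera gave this list an adjusted p of 6.35e-07, and adjusted p = 0.492 with an estimated correlation. Cyp2b10, inducible by drugs, had 3 reads in HFD and 112 in HFD_WTE, a ratio of 38.1 with an exact interval of 12.7 to 188 (adjusted p = 0.242). Macrophage markers had a median of -0.53, with none of 18 called in edgeR, 3 at an unadjusted p under 0.05, 0 called in DESeq2 or over the list alone, and C1qc at 18.5 ± 2.51 and 10.3 ± 3.55 CPM (camera adjusted p = 0.000207, and adjusted p = 0.554 with an estimated correlation). Cfd, the single tested adipocyte marker, measured 33.7 ± 14.1 CPM in HFD and 2.09 ± 1.65 in HFD_WTE. It was called in neither edgeR (adjusted p = 0.326) nor DESeq2 (adjusted p = 0.12). Camera gave adjusted p = 0.000835, and adjusted p = 0.143 in the test run with an estimated correlation, which a single gene does not have. With 1 tested gene, these values say nothing about the list as a whole. The adipocyte list of 7 genes summed to 42.8 ± 19.3 and 2.74 ± 2.02 TPM in these groups, but its members other than Cfd had too few reads to be tested.

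A further 10 lists passed camera but lost the call when at least 1 library was left out, with no member called in edgeR over all genes. At an unadjusted p under 0.05 they held 5 PPAR-alpha, 5 lipid droplet, 3 endoplasmic reticulum, 2 stellate, 2 endothelial, 3 acute phase, 5 antioxidant, 0 respiratory chain, 3 fatty acid uptake and 5 glucose genes. DESeq2 called 1 fallen lipid droplet gene, 1 risen acute phase gene and 2 risen genes each for antioxidant and fatty acid uptake, and 0 in the other 6 lists. Adjusted over the list alone, Cidea and Col3a1 fell, Nqo1, Gstm1, Gstm2, Gstm3, Vldlr and Angptl8 rose, and no gene passed in the other 6. The lists of PPAR-alpha targets (camera adjusted p = 0.000207), lipid droplet (0.00572), endoplasmic reticulum stress (0.000207), stellate cell and matrix (0.00873) and sinusoidal endothelium (0.0167) were lower. The highest adjusted p with a library left out was 0.832, 0.362, 0.238, 0.0579 and 0.502 for these 5, without HFD replicate 1, HFD replicate 1, HFD_WTE replicate 1, HFD_WTE replicate 3 and HFD replicate 1. With an estimated correlation, adjusted p = 0.554, 0.52, 0.52, 0.502 and 0.584. The lists of acute phase proteins (0.00713), antioxidant and NRF2 targets (0.00701), respiratory chain (0.0171), fatty acid uptake and lipoproteins (0.046) and glucose metabolism (0.046) were higher. Their highest adjusted p with a library left out was 0.784, 0.182, 0.346, 0.158 and 0.2, without HFD_WTE replicate 3, HFD replicate 1, HFD replicate 1, HFD_WTE replicate 1 and HFD_WTE replicate 1; the direction of the acute phase list turned there. Calls were also lost without HFD_WTE replicate 1 for PPAR-alpha targets (adjusted p = 0.136), lipid droplet (0.123) and endothelium (0.108), without HFD_WTE replicate 2 for respiratory chain (0.224), antioxidant (0.0611), fatty acid uptake (0.114) and glucose metabolism (0.0782), and without HFD replicate 1 for fatty acid uptake (0.127) and glucose metabolism (0.113). Without HFD replicate 2 they were lost for endothelium (0.0599), fatty acid uptake (0.0618) and glucose metabolism (0.0599), and without HFD replicate 3 for acute phase proteins (0.169), fatty acid uptake (0.108) and glucose metabolism (0.108). With an estimated correlation, adjusted p = 0.584, 0.554, 0.584, 0.593 and 0.492. The other 17 lists did not pass, with adjusted p from 0.0501 to 0.995.

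Several members with the smallest p of their list were not called in edgeR. Cidea, a lipid droplet protein, had 70 reads in HFD and 2 in HFD_WTE, a ratio of 34.3 with an exact interval of 9.15 to 289 (edgeR adjusted p = 0.196). The summed adipocyte list, of which only Cfd was tested, was also lower in HFD_WTE. Vldlr, a lipoprotein receptor, measured 0.613 ± 0.238 and 4.17 ± 0.961 CPM, Gstm2 17.9 ± 4.28 and 44.7 ± 11.8, Dio1 172 ± 42.7 and 47.0 ± 18.4, Cyp7b1 259 ± 58.4 and 81.3 ± 38.3, Col3a1 10.2 ± 1.41 and 5.58 ± 0.770, and Fabp1 4588 ± 1064 and 2699 ± 403 CPM. Of these 7, DESeq2 called Cidea (adjusted p = 0.021), Vldlr (0.000223), Gstm2 (0.00063), Dio1 (9.46e-06) and Cyp7b1 (0.000174). In the bile acid and energy expenditure lists edgeR called 0, with 3 and 5 genes at an unadjusted p under 0.05, and DESeq2 called 1 fallen gene each. Fasn (100.3 ± 12.3 and 99.4 ± 31.9 CPM), Scd1 (924 ± 585 and 1247 ± 509), Srebf1 (70.1 ± 19.3 and 121 ± 70.5), Cpt1a (209 ± 30.4 and 209 ± 33.6), Cd36 (28.9 ± 8.97 and 21.4 ± 11.4), Cyp7a1 (17.4 ± 8.39 and 20.2 ± 13.2) and Fgf21 (23.3 ± 28.2 and 4.55 ± 1.501) did not pass in edgeR or DESeq2. Values for the remaining lists were Orm3 3.32 ± 0.648 and 12.5 ± 11.4 CPM, Mid1ip1 10.1 ± 2.54 and 23.1 ± 11.1, Gpt 223 ± 22.1 and 326 ± 19.5, Sel1l 162 ± 18.5 and 95.7 ± 27.3, Ifi27 91.5 ± 5.97 and 64.2 ± 11.02, Il1a 2.70 ± 0.354 and 1.51 ± 0.414, Acsl1 1104 ± 167 and 656 ± 196, Ehd3 30.1 ± 5.34 and 22.1 ± 1.51, Cry2 29.2 ± 6.41 and 38.1 ± 1.73, Aurka 1.13 ± 0.489 and 1.82 ± 0.104, and Cox5a 71.2 ± 14.0 and 88.6 ± 16.2; of these DESeq2 called Orm3 (adjusted p = 0.0122). The number of calls was 19 without either ND replicate, 3, 1 and 2 without HFD replicates 1, 2 and 3, and 3, 1 and 1 without HFD_WTE replicates 1, 2 and 3; Moxd1 passed in all of these. DESeq2 called 73 genes.

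The series title asks whether the extract counters the diet. Of the 144 genes called in HFD against ND, 105 (72.9%) had a fold change of the opposite sign in HFD_WTE against HFD. Both comparisons use the same HFD libraries, which gives opposite signs by chance. Simulations with the diet difference kept and no extract effect gave 65.9% (64.1 to 68.8% over 50 simulations) over the more numerous genes they called. Over as many genes as were called in the data, a measure added after the data were seen, they gave 66.0% (55.6 to 75.7%). Simulations with no effect in any group gave more, 88.9% (81.9 to 95.1%) over as many genes and 89.3% over the few they called, 0.8 on average. Over all 13127 tested genes, 52.9% had opposite signs, below the 58.0% of the simulations with the diet difference kept (56.9 to 58.9%) and the 64.7% with no effect (63.6 to 65.8%). Over all tested genes, the covariance of the 2 sets of log2 fold changes was -0.0899, against -0.0809 ± 0.00583 (SD over simulations) with the diet difference kept and -0.0803 ± 0.00375 with no effect. Their correlation across genes, which are not independent, was -0.235, against -0.225 and -0.438. Over the 144 called genes the covariance was -2.67, against -0.646 (-1.21 to -0.241) over as many genes of smallest p in simulations with the diet difference kept, and -0.3665 over the 1387 genes that these called on average. With no effect it was -1.01 (-1.77 to -0.622) over as many genes, and -8.92 (-27.2 to -1.28) over the called genes of the few simulations that called more than 2. The observed covariance over the 144 called genes includes large fold changes of uncertain size from few reads. Among them are Moxd1 (8.68 and -11, with 1 read in ND and 0 in HFD_WTE) and Cyp2b10 (-5.8 and 5.07, with 3 reads in HFD). The share was 46.7% without ND replicate 1. The 3 HFD libraries cannot be split into parts of at least 2, so fits chosen after the data were seen gave 1 HFD library to one comparison and the other 2 to the other. In these 6 fits, which share no library between the comparisons, the covariance over all genes lay between -0.0426 and 0.0401, and 43.6 to 50.3% of all genes had opposite signs. The diet comparison then called 1 to 64 genes. Moxd1, Selenbp2 and Ugt2b38 were called in both comparisons of the full data with opposite signs. Independent lists would share 0.0229 genes in this way. Simulations that share the HFD libraries gave 0.34 on average and at most 5 with the diet difference kept, and 0.08 and at most 1 with no effect.

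**Figure D3:**
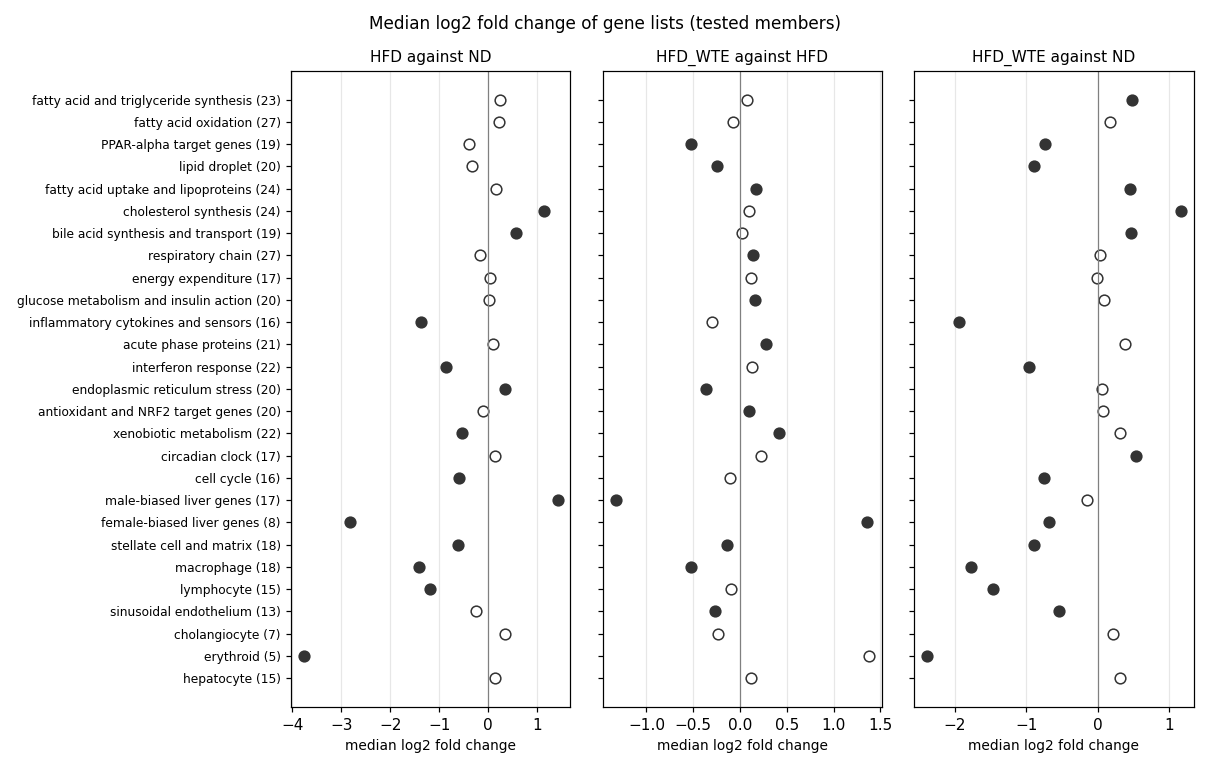
Median log2 fold change (horizontal axis, with its own scale in each panel) of the tested members of each list with at least 5 of them, whose number is in parentheses, in the 3 comparisons. Filled points have a camera adjusted p under 0.05 with the preset correlation and open points do not; male-biased genes have a median of 1.42 in HFD against ND and -1.33 in HFD_WTE against HFD.

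The third comparison asked what still differed from the normal diet in mice given the extract. Enho, which encodes the secreted peptide adropin, rose from 5.38 ± 0.296 CPM (SD, n = 2) in ND to 39.3 ± 9.93 CPM (SD, n = 3) in HFD_WTE (log2 fold change 2.86 ± 0.30, edgeR adjusted p = 0.00544). Cyp2b9 fell from 27.3 ± 0.935 to 1.10 ± 0.662 CPM (-4.63 ± 0.54, adjusted p = 0.0111), Col1a2 from 15.6 ± 0.897 to 4.17 ± 0.732 CPM and Lpl from 44.1 ± 5.09 to 14.7 ± 3.08 CPM (both adjusted p = 0.0193). In all, 410 genes were called, 161 higher and 249 lower. An unadjusted p under 0.05 was reached by 2881 genes, where 656 would be expected if no gene differed. The other largest rises were Sssca1 (second gene model, 3.23 ± 0.66), Idi1 of isoprenoid synthesis (3.13 ± 0.72), Ugt1a5 (2.78 ± 0.47) and Cyp2d34 (2.66 ± 0.53). The other largest falls were Cdkn1a, a cell cycle inhibitor (-4.23 ± 0.78), Cd300e (-4.09 ± 0.79), Dusp8 (-4.06 ± 0.91) and Cd207 (-3.96 ± 0.72). The 2 ND libraries differed widely in several of these genes. Cdkn1a measured 48.7 ± 57.15 CPM in ND and 2.59 ± 1.19 in HFD_WTE, Cd300e 3.97 ± 4.26 and 0.229 ± 0.149, and Cd207 7.48 ± 6.44 and 0.476 ± 0.173.

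In macrophage markers, 10 of 18 fell over all genes and 16 over the list alone, among them Vsig4 (23.3 ± 14.5 to 3.78 ± 1.08 CPM). Camera gave adjusted p = 8.26e-18, and adjusted p = 0.305 with an estimated correlation. Of 18 stellate cell and matrix genes 5 fell (Col1a1, Col1a2, Col3a1, Lrat and Reln), of 15 lymphocyte markers 3 (Gzma, Gzmb and Nkg7), of 16 inflammatory genes 5 (Il1a, Ccl5, Cxcl9, Vcam1 and Cd14) and of 22 interferon response genes 2 (Irf7 and Oasl2). Over each list alone, 8, 3, 12 and 11 fell, and 1 inflammatory gene rose. Camera adjusted p was 2.46e-08, 1.07e-06, 5.95e-07 and 1.07e-06 for these 4 lists, and adjusted p = 0.305, 0.305, 0.321 and 0.442 with an estimated correlation. The interferon list gave 0.22 without ND replicate 2. Of 24 cholesterol synthesis genes, 4 rose (Pmvk, Idi1, Fdps and Tm7sf2) and 17 over the list alone (camera adjusted p = 4.51e-11, and adjusted p = 0.367 with an estimated correlation). Male-biased genes did not pass (camera adjusted p = 0.878); none was called in edgeR or DESeq2 and 2 had an unadjusted p under 0.05.

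A further 10 lists passed camera and lost the call when at least 1 library was left out, an ND library in each case. Higher were fatty acid synthesis (adjusted p = 0.0462; Fasn 42.6 ± 5.08 to 99.4 ± 31.9 CPM and Mid1ip1 5.06 ± 2.30 to 23.1 ± 11.1 CPM rose), fatty acid uptake and lipoproteins (0.00184; Lrp1 rose, 331 ± 30.7 to 802 ± 44.8 CPM), bile acid synthesis (0.00781; Nr0b2 rose, 25.2 ± 4.99 to 55.6 ± 15.7 CPM) and circadian clock (0.0191; Per3 and Bhlhe41 rose, Cry1 fell, and over the list alone 9 rose and 3 fell). Lower were PPAR-alpha targets (0.00803; Ucp2 and Acot2 fell), lipid droplet (0.00188; Lpl and Hilpda fell), cell cycle (0.000255; Mki67 fell, 7.52 ± 6.97 to 0.865 ± 0.625 CPM), female-biased genes (0.00803; Cyp2b9 fell), sinusoidal endothelium (0.00188; Pecam1 fell, 12.7 ± 1.23 to 5.42 ± 0.628 CPM) and erythroid markers (0.000188; none called in edgeR, 5 at an unadjusted p under 0.05, 0 in DESeq2, and Hba-a1 at 179 ± 116 and 36.1 ± 37.4 CPM). Adjusted over the list alone, 3 genes rose and 1 fell in fatty acid synthesis, 1 rose in fatty acid uptake, 3 rose in bile acid synthesis, 1 rose and 4 fell among PPAR-alpha targets, and 2 rose and 7 fell in lipid droplet, while 6 cell cycle, 2 female-biased, 3 endothelial and 5 erythroid genes fell. Without ND replicate 2 the adjusted p was 0.248, 0.235 and 0.606 for fatty acid synthesis, fatty acid uptake and bile acid synthesis and 0.0597 for cell cycle. Without ND replicate 1 it was 0.277 for circadian clock, 0.555 for PPAR-alpha targets, 0.277 for lipid droplet, 0.484 for female-biased genes, 0.0699 for endothelium and 0.0504 for erythroid markers. Fatty acid synthesis was also lost without ND replicate 1 (0.0736), HFD replicate 1 (0.0787), HFD_WTE replicate 1 (0.162) and HFD_WTE replicate 2 (0.111), and PPAR-alpha targets without HFD_WTE replicate 1 (0.137). With an estimated correlation, adjusted p = 0.586, 0.445, 0.586 and 0.321 for the 4 higher lists and 0.662, 0.37, 0.37, 0.321, 0.473 and 0.321 for the 6 lower ones.

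The other 16 lists did not pass, with adjusted p from 0.212 to 0.985. In them Gstm2 rose, and Gsta2, Cyp3a11, Saa3, Ucp2 and Atf3 fell; Atf3, a stress-induced transcription factor, went from 21.1 ± 19.1 to 1.56 ± 0.365 CPM (adjusted p = 0.0304). Of the 75 genes higher in HFD than in ND, 42 were also among the 161 higher in HFD_WTE (independent lists would share 0.92), and of the 69 lower genes, 42 were also among the 249 (1.31). In all 84 calls were shared. Simulations with no effect in any group shared 0.14 on average, but called only 0.8 and 0.62 genes in these comparisons. Those with the diet difference kept and no extract effect shared 936 of the 1387 and 1395 calls they made. The covariance of the log2 fold changes over all genes was 0.499, against 0.128 with no effect and 0.705 with the diet difference kept. Part of the overlap may come from the ND libraries that both comparisons use. In fits chosen after the data were seen, each comparison had its own ND library. With ND replicate 1 for HFD, 16 calls were shared (51 and 1046 calls, 2.21 for independent lists). With ND replicate 2 for HFD, 15 were shared (696 and 64 calls, 1.83). The covariance was 0.254 and 0.267. The calls numbered 1077 without ND replicate 1, 64 without ND replicate 2, 97 and 42 without HFD replicates 2 and 3, and 4 and 2 without HFD_WTE replicates 1 and 2, and DESeq2 called 1149. Without HFD replicate 1 and without HFD_WTE replicate 3 the calls numbered 322 and 338. With total counts in place of TMM, which moved the median of all genes to 0.14, 63.2% of the calls were higher, against 39.3%.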

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

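All but 3 kinds of alternative were set before the data were examined; limma-voom with sample weights, the list minimum of 5 members and fits with separate libraries for 2 comparisons were added afterwards. The cause of a change was not tested except where stated. For HFD against ND, calls went from 144 to 520 with no low-count filter, 733 in DESeq2, 75 and 98 in limma-trend on log2(TPM + 1) and log2(TPM + 0.1), 79 with only the 2 groups' libraries, 31 with the replicate block and 24 with sample weights, and from 6 to 724 with a library left out. For HFD_WTE against HFD, 6 calls became 49 with no filter, 73 in DESeq2, 3 in limma-trend on log2(TPM + 1), 20 with only the 2 groups' libraries, 3 with the replicate block, 52 with sample weights, and 1 to 19 with a library left out. For HFD_WTE against ND, 410 calls became 844 with no filter, 1149 in DESeq2, 248 in limma-trend on log2(TPM + 1), 27 with only the 2 groups' libraries, 150 with the replicate block, 98 with sample weights, and 2 to 1077 with a library left out. RLE, removal of mitochondrially encoded and Mup genes, the stricter filter, the length offset, total counts and the 2-fold threshold stayed within 1.5 times. Limma-trend on log2(TPM + 1) put 80% and 75.4% of the calls against ND on the higher side, and on log2(TPM + 0.1) 81.6% and 79.2%, against 52.1% and 39.3%; it brought the median of all genes to as much as 0.20.

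The share of diet genes with the opposite sign was 57.3% in DESeq2 and 46.7 to 84.4% with a library left out. With separate HFD libraries it was 100, 88.9 and 66.7% with HFD replicates 1, 2 and 3 alone for the diet (1, 9 and 3 genes called) and 59.4, 47.6 and 83.3% with each alone for the extract (64, 21 and 6 genes). With an estimated correlation, 13, 15 and 16 list calls became 0, 1 and 0, and with fry, which tests whether a list moves on balance without comparing it with other genes, 0, 0 and 1. With a library left out they ranged over 11 to 16, 8 to 18 and 9 to 16. The acute phase list turned direction in HFD_WTE against HFD without HFD_WTE replicate 3 (adjusted p = 0.784, against 2.12e-05 as the lowest with another library left out). No named gene past the threshold in either fit turned; 20 values past it in neither changed sign. Of 20 named calls in HFD against ND, Cyp2b9, Lpl and Moxd1 passed in every alternative run, as did Moxd1 in HFD_WTE against HFD and Enho in HFD_WTE against ND. Where 1 ND library was left, it was assumed to vary like the other groups.

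The titles tie same-numbered libraries by number only. The correlation of their deviations from the group means was -0.105 to 0.176 over 7 pairs, over 0.1 in 2. Both of these were pairs of ND with HFD (0.176 and 0.126 for replicates 1 and 2), and they alone correlated best with their own number. With only 2 ND libraries, the deviations of one mirror those of the other, so these 2 pairs are not separate observations. The pairs with HFD_WTE gave at most 0.00288, so a link between same-numbered ND and HFD libraries stays open. Among list calls, the replicate block ended that of endoplasmic reticulum stress in HFD against ND (adjusted p = 0.0891), added fatty acid uptake and lipoproteins there, and changed no other. At 18954071 to 24112000 reads per library, genes with few reads, such as Moxd1 outside HFD, are limited by counting.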

Other observations

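All tests in this part except the splits of the libraries and the length trend were chosen after the result was seen. Pdk4, Igfbp1 and Fgf21, picked after their values were seen, differed between libraries of a group. Pdk4, which restrains glucose oxidation, stood at 142 CPM in ND replicate 1 and 18.8 in ND replicate 2, at 91.2 in HFD replicate 1 and 1.90 and 2.02 in HFD replicates 2 and 3, and at 2.58, 1.996 and 5.63 in the HFD_WTE libraries. Igfbp1, which binds insulin-like growth factors, stood at 346 and 69.5 CPM in ND, at 279, 15.8 and 17.1 in HFD and at 31.9, 31.7 and 94.8 in HFD_WTE. Fgf21 stood at 55.5 CPM in HFD replicate 1 and at most 11.3 elsewhere. The labels used here give no feeding or collection time.

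Male-biased liver genes were lower in HFD_WTE than in HFD. Counts taken up by abundant Mup genes do not account for the other members, since the Mup share of reads, HFD_WTE minus HFD, was -9.43 ± 0.811 (SE) percentage points, a difference that would raise the others. Reads shared between near-identical copies do not account for the members without such copies (C6, Nudt7, Cyp7b1, Susd4 and Cyp2u1), whose median log2 fold change was -1.20. The SE of their mean, over genes and not over samples, was 0.21. Libraries from females do not either, since the library with the fewest Y-linked reads held 1493. A shift of sex-biased expression may be involved, as 8 of 8 female-biased genes had positive fold changes, but housing, age and time of collection remain open and untested, and of the 10 splits of the 6 libraries only 1, the real one, called as many as 6 genes (highest other 1), too few splits for a share under 0.05.

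Macrophage, lymphocyte and erythroid lists were lower in HFD than in ND by camera with the preset correlation, but not with an estimated one (adjusted p = 0.285, 0.265 and 0.285), and edgeR called 1 of 18, 1 of 15 and 4 of 5 members. A lower share of hepatocytes as the only cause would raise the markers of every other cell type alike. Endothelial markers, however, lay 1.10 ± 0.18 (SE over genes) above macrophage markers in mean log2 fold change. As a part of the cause it was not excluded. Stellate (18 of 18) and endothelial markers (10 of 13) also had negative fold changes, while 5 of 7 cholangiocyte markers had positive ones. Blood left in the ND livers would not bring markers of resident macrophages (Clec4f, Vsig4, Cd5l and Timd4), whose median was -1.34. The SE of their mean, over genes and not over samples, was 0.42. For the haemoglobin genes, blood could not be excluded: Alas2, also held by young red cells, had a log2 fold change of 0.38 ± 0.25, which decides neither way. Without ND replicate 2, 1 ND library was left. The mean log2 fold changes were then -0.66 ± 0.09 (macrophage, against -1.37 with both) and -1.11 ± 0.26 (lymphocyte). These SEs are over genes and do not measure the spread between samples. ND replicate 1 summed to 215 TPM of macrophage markers, against 202 in HFD replicate 1, and to 25.8 TPM of lymphocyte markers, against at most 13.8 in HFD. Mitochondrially encoded genes took 436556 TPM in ND replicate 1 and 237586 in HFD replicate 1, which lowers the other sums more in ND replicate 1. The closeness of 215 and 202 TPM is therefore no sign of equal macrophage levels. ND replicate 2 was thus not alone in its higher lymphocyte sum, but 1 library cannot decide this for the macrophage list. ND replicate 2 alone also remains open for the inflammatory and interferon lists, which lost their calls without it, as does an untested diet effect on immune cells.

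The mitochondrially encoded share was higher in ND. More mitochondria as a whole would raise the nuclear-encoded respiratory chain genes by about as much. Their mean log2 fold change in HFD against ND, however, lay 1.15 ± 0.07 (SE over genes) above that of the mitochondrially encoded genes. This SE does not measure the spread between samples. A trend with transcript length, as RNA quality can give, was small (Spearman's rho across genes 0.052). A diet effect on mitochondrial transcripts alone and a difference in RNA preparation without a length trend may both remain and were not tested.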
